A study of Mus musculus with 797 samples.

How the data were processed

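Single nuclei were sorted by flow cytometry from brains of C57Bl/6J mice that had received 1 recombinant adeno-associated virus (AAV). Each virus carried an enhancer or promoter driving H2B-SYFP2, a yellow fluorescent protein fused to a histone so that it marks the nucleus, in the blood-brain-barrier crossing capsid PHP.eB. Per the labels, the dose was 5e11 vector genomes per mouse and nuclei were taken 3 to 4 weeks later. The 797 nuclei analysed here are all labelled striatum and fall under 20 vector labels of 39 or 40 nuclei each.

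Full-length cDNA was made with SMART-Seq v4 and libraries with Nextera XT, per the labels. The deposited values are raw read counts per gene and nucleus, without molecular identifiers, so PCR copies of 1 molecule are counted separately. The submitters' processing notes name STAR 2.7.2a and the mouse build mm10. The read counter, its annotation, its strand setting and whether intronic reads were counted are not given in the sources used here. Unspliced RNA is abundant in nuclei, so the treatment of introns could change the level of long genes; without a stated strand setting, reads of overlapping genes cannot be told apart. The table of counts holds 2501 columns; 797 were matched to the samples by library name, and the other 1704 were not used here. Of 32285 gene rows, 32158 were given a symbol by Ensembl identifier, and the rows without one held 0.0931% of the reads. Gene positions are those of GENCODE release M21 on mm10, counted from 1.

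Nuclei with fewer than 1000 genes or fewer than 50000 reads were left out: 8 nuclei fell under the first limit and 9 under the second, 16 nuclei in all, which left 781. Counts were divided by the nucleus total and scaled to CPM, counts per 1e6 gene reads, a pseudocount of 1 was added and log2 taken. Clusters came from 3000 variable genes, 30 principal components, a shared-neighbour graph of 15 neighbours and the Leiden method at resolution 1 with seed 0 (igraph 0.11.9, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, Python 3.11.15). A cluster was called X-like from marker lists fixed before the data were examined. The limits of that naming were set after the data had been seen: at least 3 markers of the list, each read in at least 10% of the cluster's nuclei and raised by at least 0.3 log2 units. Among the lists that passed, the one with the largest mean difference from the other nuclei gave the name. A stricter rule held for the spiny projection neuron lists. They could pass only with 3 raised markers of the D1 or D2 list and 3 of the general list. A cluster counted as GABAergic where at least 3 genes of the fixed GABAergic list were read in at least 30% of its nuclei. A GABAergic cluster without 3 raised markers of 1 interneuron or spiny projection neuron list stayed unnamed. So did a cluster that passed for 1 interneuron list but had at least 3 raised markers of another, not shared with the first. For all alternatives clusters were named on the log2(CPM+1) scale, a choice also made after seeing that naming on log2(CPM+10) left 1 glutamatergic cluster without a name; the closing section gives both versions. No doublet caller was run, since each library was made from 1 sorted nucleus.

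The steps were tested on simulated data. For hSyn1 against CMV, 200 of 1433 genes were changed: the sign was right for 67 of 68 genes changed by a factor of 2, for 63 of 63 at 4 and for 69 of 69 at 8. A difference over 1 on the log2 scale with the right sign was reached by 26 of the 68, by all at 4 and at 8, and, in either direction, by 23 of the 1233 unchanged genes. All 20 genes that the naming rule picked were among those changed. Both simulated groups started from the pooled profile of both vectors, with no mixture of cell classes, and differences were centred on their median. The real comparison had such a mixture and was not centred, so these counts do not give its error rates. In simulated classes of 80 nuclei each, 80 glutamatergic neurons, 80 Pvalb/Pthlh interneurons, 79 Sst/Npy interneurons, 80 D1 and 80 D2 spiny projection neurons got their own name. Each simulated class was made by raising the list that names it, so this recovery checks the code and not the lists. An earlier form of the naming rule had named none of the simulated D1 nuclei and was corrected; the names of the real clusters did not change with that correction.

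The labels name no animal, so the nuclei of 1 vector are 1 sample: no test was run between vectors on nuclei, and no p-value or standard error was made from them. Shares of nuclei carry exact Clopper-Pearson 95% intervals and summed reads exact Poisson 95% intervals; for a share of 0, the limit is 3 nuclei of the total. All of these cover counting error only. The Poisson intervals take each read as independent, which PCR copies of 1 molecule are not, so they are too narrow. Levels are means of log2(CPM+1) with the SD over nuclei. Genes per nucleus were compared after thinning each nucleus to 100000 reads, which left out 5 nuclei. The only test is an exact two-sided permutation test over the 16 AiE enhancers, with 1 value per vector. Named genes follow a rule fixed before the data were examined: for each vector the 2 genes furthest above the equal-weight mean of the other 19 vectors; for both reference pairs the 10 largest differences in each direction; for each AiE enhancer against CMV the 2 largest in each direction. A gene had to have a read in at least 50% of the nuclei concerned. Genes of the Y chromosome, Xist, predicted genes, mitochondrial genes and rows without a symbol, 10695 rows in all, were not eligible. Not every gene that the rule picked is named. From each fixed list the most abundant members were taken, and from the lists of spiny projection neurons, interneurons and glia any member.

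The balance of D1 to D2 spiny projection neurons and the levels within those classes, both planned, could not be computed because no such class was found; levels within glutamatergic and GABAergic nuclei were computed in their place. Alternatives covered the filter on nuclei, the clustering settings, the pseudocount, thinning, classes taken from marker levels without clustering, and the library set. The library set is taken from the prefix of the library names: set A (prefix S40331) held 528 nuclei, set B (S40317) 181 and set C (S40330) 88.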

Results

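The data were read counts from 797 single nuclei of mouse brain, each sorted for the yellow nuclear reporter of 1 AAV vector. The 20 vector labels comprise 4 reference elements and 16 AiE enhancers. CMV is a viral promoter in wide use, hSyn1 the human synapsin 1 promoter used for neurons, and hI56i and DLX2.0 are elements from the Dlx genes used for forebrain GABAergic neurons. Nuclei had 8712 to 666436 gene reads with a median of 290674, and a median of 2792 genes. The median per vector lay between 216841 reads for AiE0682h and 349910 for DLX2.0. No 2 nuclei had identical counts. Each vector is 1 sample without a named animal, so the values below have no replicate check and the intervals cover counting error only.

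The first question was which cells the sorted nuclei came from. Glutamatergic neuron-like nuclei made up 418 of the 781 nuclei kept (53.5%, 95% interval 50.0 to 57.1). Pvalb/Pthlh interneuron-like nuclei made up 22.5% (19.6 to 25.6), Sst/Npy interneuron-like nuclei 11.5% (9.37 to 14) and other GABAergic interneuron-like nuclei 7.81% (6.03 to 9.92). A further 24 GABAergic nuclei (3.07%) stayed unnamed, 11 nuclei were astrocyte-like and 1 was like an oligodendrocyte precursor, with cell cycle genes such as Cdk1 and Rrm2 among its leading genes. No cluster was like a spiny projection neuron (SPN), the GABAergic principal neuron of the striatum, although every nucleus is labelled striatum. The rule for SPN names was stricter than for other classes. In the glutamatergic clusters of 120, 106, 73, 68 and 42 nuclei, the general SPN list had the largest mean difference among the lists that did not give the name. The label and the expression disagree, so the nuclei are called "labelled striatum" below.

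Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons (ENSMUSG00000070570, chromosome 7, 45163949 to 45176142, mm10), had a read in 443 nuclei (56.7%, 53.2 to 60.2). After thinning the share was 56.3%. The cortical transcription factor genes Neurod6, Neurod2 and Tbr1 had reads in 26%, 22.8% and 20.4% of nuclei. Within glutamatergic nuclei these shares were 47.1%, 41.4% and 36.1%, and within GABAergic nuclei 1.71%, 1.42% and 2.28%. Gad1, which makes GABA (ENSMUSG00000070880, chromosome 2, 70553072 to 70602014), had a read in 43.1% of nuclei: 90.9% of the GABAergic and 4.31% of the glutamatergic ones. Median depth was 317551 reads in GABAergic and 278957 in glutamatergic nuclei.

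Genes that mark SPNs were rare. The dopamine receptor gene Drd1 (ENSMUSG00000021478, chromosome 13, 54051183 to 54055705) had a read in 47 nuclei (6.02%, 4.45 to 7.92), and Drd2 in 5 nuclei (0.640%, 0.208 to 1.49). The adenosine receptor gene Adora2a (ENSMUSG00000020178, chromosome 10, 75316877 to 75334784) and Isl1 had reads in 0 of 781 nuclei, which allows a share of up to 0.384%. Ppp1r1b, which encodes DARPP-32, was read in 9.86% of nuclei and Rgs9 in 11.4%. Other members of the SPN list are also used by cortical neurons, and Pde10a, Phactr1, Arpp21 and Foxp1 had reads in 75.2%, 73.2%, 59.4% and 59.4% of nuclei. Chat, the marker of cholinergic interneurons, was read in 1 nucleus. Markers of oligodendrocytes and microglia that are restricted to those cells were also rare, with Mog in 1.79% and P2ry12 in 1.66% of nuclei.

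**Figure D1:**
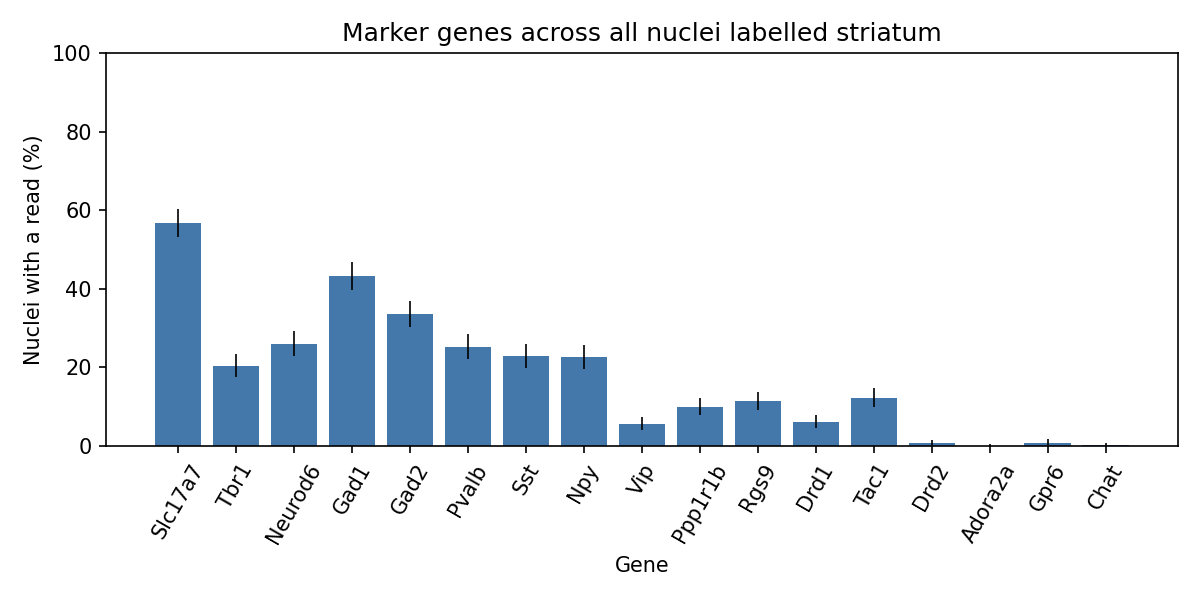
Share of the 781 nuclei labelled striatum with a read of each gene (bars, %), with exact 95% intervals for counting error (lines). Slc17a7 reached 56.7% and Gad1 43.1%, while Drd2 stood at 0.640% and Adora2a at 0.

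The next comparison set the 4 reference vectors side by side. GABAergic nuclei made up 94.9% of nuclei labelled hI56i (37 of 39, 82.7 to 99.4), 79.5% for DLX2.0 (31 of 39, 63.5 to 90.7), 65% for CMV (26 of 40, 48.3 to 79.4) and 50% for hSyn1 (19 of 38, 33.4 to 66.6). Pvalb/Pthlh interneuron-like nuclei led 3 of the 4, with 48.7% for hI56i, 42.5% for CMV and 33.3% for DLX2.0, and took 15.8% for hSyn1, where glutamatergic nuclei were as many as GABAergic ones. Sst/Npy interneuron-like nuclei made up 28.2% for DLX2.0, 23.1% for hI56i, 21.1% for hSyn1 and 7.5% for CMV. The intervals of neighbouring vectors overlap. With classes from marker levels without clustering the GABAergic shares were 46.2% for hI56i, 43.6% for DLX2.0, 37.5% for CMV and 34.2% for hSyn1, and the Pvalb/Pthlh shares 23.1% for hI56i, 25% for CMV and 17.9% for DLX2.0. That method gave each nucleus to the best-scoring of all class lists, SPN and glial lists included, so these shares can be lower. The glutamatergic share of hSyn1 came to 10.5% by marker levels and 28.9% with clusters named on log2(CPM+10). The CMV and hSyn1 shares differed between library sets: GABAergic nuclei were 23 of 24 for CMV in set A and 3 of 16 in set C, and for hSyn1 0 of 10 in set A and 14 of 20 in set C.

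Among the 16 AiE enhancers the question was which class each vector label held. Glutamatergic neuron-like nuclei were all 40 of AiE0401h (100%, 91.2 to 100), 97.4% of AiE0387m (86.2 to 99.9), 95% of AiE0078h and of AiE0445h_3xC2 (83.1 to 99.4 for each), 89.7% of AiE0779m (75.8 to 97.1) and 85% of AiE0140h (70.2 to 94.3). They also led AiE0447h with 76.3% (59.8 to 88.6), AiE0391h with 70.3% (53 to 84.1), AiE0743m_3xC2 with 57.5% (40.9 to 73.0) and AiE0410m with 42.5% (27 to 59.1). In the other 6 enhancers Pvalb/Pthlh interneuron-like nuclei were the largest class, from 35.9% for AiE0390m (21.2 to 52.8) to 46.2% for AiE0475m (30.1 to 62.8). The GABAergic share as a whole was 84.6% for AiE0450h, 78.9% for AiE0600m, 76.9% for AiE0682h, 71.8% for AiE0452h, 69.2% for AiE0390m, 57.5% for AiE0410m and 56.4% for AiE0475m. AiE0410m thus had more GABAergic than glutamatergic nuclei, spread over several classes. This majority came from set B, with 14 of 16 GABAergic nuclei, while set A had 9 GABAergic and 15 glutamatergic nuclei of 24. Astrocyte-like nuclei, found in set B alone, were most frequent for AiE0140h (4 of 40). The unnamed GABAergic nuclei, from the same set, were 10 of 37 for AiE0391h, 5 of 39 for AiE0452h, 4 of 38 for hSyn1 and 3 of 39 for AiE0779m. Their cluster was led by mitochondrial genes such as mt-Nd1 and mt-Cytb (median share 2.08% of reads), and Sst was read in 66.7%, Npy in 54.2% and Pvalb in 41.7% of its nuclei. With classes from marker levels without clustering, the 10 labels led by glutamatergic nuclei had shares of 17.5% (AiE0401h) to 45% (AiE0445h_3xC2), with 36.8% for AiE0387m, and the 6 led by Pvalb/Pthlh interneuron-like nuclei had 7.69% (AiE0452h) to 25.6% (AiE0475m). With clusters named on log2(CPM+10) the glutamatergic share was 45.9% for AiE0391h and 53.8% for AiE0779m.

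**Figure D2:**
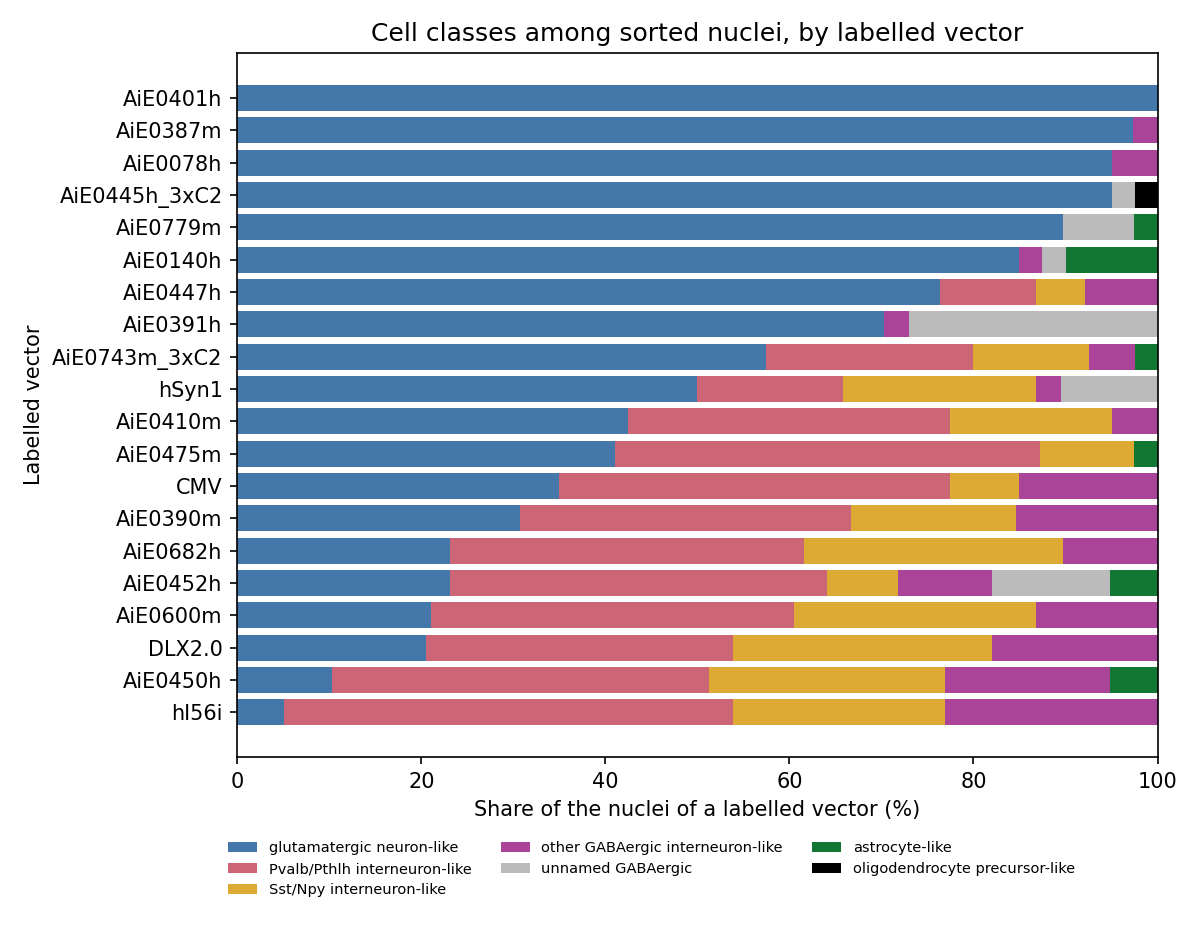
Share of nuclei in each class (stacked bars, % of the nuclei of a vector label), ordered by the glutamatergic share. Labels run from hI56i with 5.13% glutamatergic nuclei to AiE0401h with 100%.

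Class shares were compared between library sets within each vector label. AiE0401h, AiE0387m and hI56i held nearly the same broad class in each set, with GABAergic shares that differed by 0, 4.55 and 12.5 percentage points. Gaps were as small for AiE0078h (8.33 points), AiE0452h (11.7), AiE0140h (12.5) and AiE0445h_3xC2 (12.5). In 6 of the 20 labels the sets were over 50 points apart. For AiE0600m 30 of 30 nuclei in set A and 0 of 8 in set B were GABAergic. For AiE0447h the order was the other way, with 1 of 30 in set A and 8 of 8 in set B. AiE0475m had 22 of 23 GABAergic nuclei in set A, 0 of 11 in set C and 0 of 5 in set B, and AiE0390m had 24 of 24 in set A and 3 of 15 in set B. A vector's overall share is therefore a mixture of sets that differ, and the labels do not say how the sets were made.

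**Figure D3:**
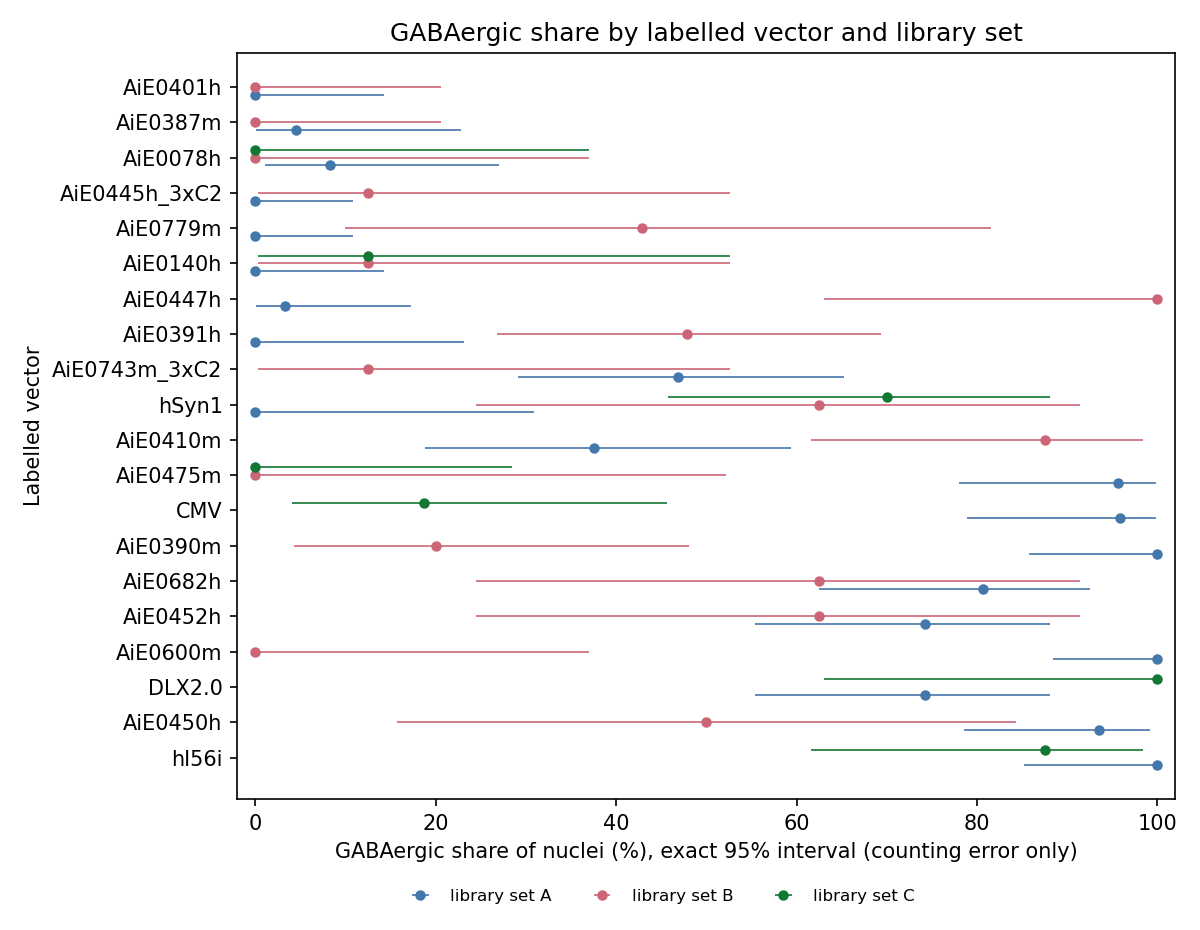
GABAergic share of nuclei (points, %) with exact 95% intervals for counting error (lines), by vector label and library set. CMV, hSyn1, AiE0390m, AiE0447h, AiE0475m and AiE0600m have sets over 50 points apart.

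The genes furthest above the other 19 vector labels followed the classes. Slc17a7 was among the leading pair of genes for AiE0387m, AiE0401h, AiE0445h_3xC2 and AiE0779m, where its mean level was 8.55 to 8.95 log2(CPM+1) against 4.91 to 4.93 in the other labels. Gad1 was among the leading pair for hI56i (8.38 ± 3.79, SD over nuclei), AiE0450h (7.99 ± 4.00), AiE0600m (7.08 ± 4.55), AiE0390m (6.73 ± 4.90) and DLX2.0 (6.72 ± 4.50), against 3.97 to 4.05 in the others. Nxph1, a neurexin ligand of inhibitory neurons, was high for hI56i (6.10 ± 4.58) and AiE0452h (5.78 ± 4.53). The immediate early genes Egr1 (8.02 ± 3.82) and Junb (6.48 ± 3.76) led AiE0078h, with 3.52 and 2.39 in the other labels. Miat, a long noncoding RNA, was read in 38 of 38 nuclei of AiE0387m, at 9.01 ± 1.33. Gpm6b (9.36 ± 1.41) and the glutamate transporter gene Slc1a2 (6.74 ± 4.45) led AiE0140h. Slc1a2 was also among the leading pair for AiE0445h_3xC2, at 7.15 ± 3.17.

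The comparison of hSyn1 with CMV addressed a neuronal promoter against a general one. The genes furthest above CMV in nuclei labelled hSyn1 were Rnf165 (4.49 ± 3.88 against 1.11 ± 2.72, a difference of 3.39), the calcium-binding protein gene Calb1 (5.27 ± 4.83 against 1.94 ± 3.85), Mrfap1 and Ensa. Myo9a, Chl1, Zdhhc17, Rab2a, Dda1 and Clcn4 followed, with differences of 3.12 down to 2.87. Furthest below were Stk38 (2.94 ± 3.52 against 5.93 ± 3.55) and Mat2a, which makes S-adenosylmethionine (6.40 ± 4.08 against 9.27 ± 2.84), then Asah1, Osbpl3, Vbp1, Prpsap1, Mbip, Mtif2, Emg1 and Pdss1. Summed over nuclei, Myo9a had 224 CPM for hSyn1 (216 to 233) and 15.5 for CMV (13.4 to 17.9), with reads in 24 of 38 and 13 of 40 nuclei. Summed reads set Myo9a further apart than its mean levels did, but brought Zdhhc17 closer, at 187 CPM for hSyn1 and 133 for CMV. Each of these 20 differences was smaller than the larger of both SDs over nuclei. The mean of the immediate early list was 2.27 ± 1.91 for hSyn1 and 1.25 ± 1.17 for CMV, and that of the cytoplasmic and mitochondrial list 3.04 ± 2.87 and 1.41 ± 0.80. The label hSyn1 has 8 nuclei of set B, where reads of cytoplasmic genes were higher, and CMV none. In set A alone, where all nuclei kept under hSyn1 were glutamatergic and 23 of 24 under CMV GABAergic, the difference of Mat2a was -6.63 and that of Chl1 0.49.

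DLX2.0 was compared with hI56i, both Dlx-derived elements. The Pvalb/Pthlh interneuron list averaged 1.77 ± 1.32 for DLX2.0 and 2.35 ± 1.53 for hI56i, and the Sst/Npy interneuron list 2.08 ± 1.97 and 2.41 ± 1.87. The glutamatergic list went the other way, with 0.90 ± 1.46 and 0.23 ± 0.72. Glutamatergic nuclei were 8 of 39 for DLX2.0 and 2 of 39 for hI56i, so the list and gene differences also carry this class make-up. Arap2 (4.38 ± 4.29 against 1.44 ± 2.96), Slc7a6os, Ensa, Mia2, Cpsf7, Eps15l1, Sec11c, Kif2a, Pfn2 and Smarca1 were furthest above in DLX2.0, by 2.94 down to 1.87. Furthest below were the ribosomal scaffold gene Rack1 (1.39 ± 3.09 against 4.61 ± 4.21), Atp11b, the phosphate exporter gene Xpr1 (0.77 ± 2.14 against 3.60 ± 3.93), Nxph1 (3.35 ± 4.23 against 6.10 ± 4.58) and the kainate receptor gene Grik2 (2.22 ± 3.57 against 4.91 ± 3.80). Yars, Tgs1, Tnik and Sem1 were also lower in DLX2.0. Each of these differences was smaller than the larger of both SDs over nuclei. Summed CPM of Xpr1 were 12.1 (10.3 to 14.1) for DLX2.0 and 145 (138 to 152) for hI56i. Those of Ensa were 269 (260 to 278) and 146 (139 to 152), a smaller gap than in its mean levels (5.57 against 3.09).

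Each AiE enhancer was set beside CMV. For AiE0078h, AiE0140h, AiE0387m, AiE0401h, AiE0445h_3xC2, AiE0447h and AiE0779m the gene furthest below CMV was Gad1, with mean levels of 0.24 to 2.05 against 5.87 ± 5.01. Its summed CPM ran from 8.19 for AiE0078h (6.66 to 9.97) and 28.5 for AiE0401h through 120 for AiE0140h, 122 for AiE0387m, 142 for AiE0445h_3xC2 and 169 for AiE0779m to 345 for AiE0447h (334 to 357), and were 926 for CMV (909 to 944). Nebl stood next to it for AiE0078h, AiE0140h and AiE0447h (1.29 to 2.74 against 6.31 ± 4.35). Above CMV were Arpp21 for AiE0387m, AiE0401h, AiE0445h_3xC2, AiE0447h and AiE0779m (7.78 to 9.32 against 4.37 ± 4.95), and Psd3 for AiE0140h, AiE0447h and AiE0779m (6.52 to 6.76 against 2.13 ± 3.81). AiE0078h had Junb (6.48 against 1.21) and Egr1 (8.02 against 3.09) furthest above. In labels rich in GABAergic nuclei the leading genes were of mixed function, such as Myo9a for AiE0600m (5.63 ± 3.45 against 1.63 ± 2.52) and AiE0410m (5.04 ± 3.80), Fam171b for AiE0390m (5.71 ± 4.23) and AiE0450h (5.55 ± 4.06), and Ddx17 for AiE0452h (7.38 ± 2.54) and AiE0475m (6.79 ± 3.15). Since CMV is itself a mixture that differs by set, a difference from it also carries its class make-up.

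Genes per nucleus at 100000 reads had medians from 2287 for AiE0447h (SD 515, 38 nuclei) to 2905 for AiE0390m (SD 954, 39 nuclei); unthinned, these were 2432 and 3114. By library set the thinned median was 3109 in set B, 2594 in set A and 2522 in set C. Set B held 38.5% of the nuclei of AiE0390m, 21.1% of AiE0447h and 0% of CMV, DLX2.0 and hI56i, so the medians per vector also carry the make-up of sets, and no range within a set was computed. Unthinned medians also differed between clusters, with 3182 genes in the Pvalb/Pthlh cluster and 2390 to 6227 in the glutamatergic clusters. Class make-up was not held fixed between vectors either.

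Levels within a class were compared in set A, among labels with at least 10 nuclei of the class. In glutamatergic nuclei the immediate early list, genes switched on by neuronal activity, had its highest mean for AiE0078h (3.41 ± 1.86, 22 nuclei), then hSyn1 (3.09 ± 2.22, 10 nuclei), and its lowest for AiE0140h (1.58 ± 1.42, 24 nuclei). Egr1 stood at 8.90 ± 3.01 for AiE0078h and 4.68 in the other 10 labels, and Junb at 6.60 ± 4.21 and 3.11. For hSyn1, Arc stood at 7.53 ± 4.40 against a mean of 5.30 in the other labels, and Egr1 at 3.71 ± 4.80 against a mean of 5.20, with AiE0779m lower at 3.24 ± 4.31. In GABAergic nuclei the list ran from 0.54 ± 0.59 for DLX2.0 to 1.15 ± 1.20 for AiE0450h. The interferon response list lay between 0.17 and 0.43 in glutamatergic and between 0.15 and 0.43 in GABAergic nuclei. The p53 response list lay between 0.80 and 1.22, and between 0.95 and 1.33.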

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

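All tests in this part were chosen after the results had been seen.

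Library set B stood out by reads from mitochondrial genes, which were not eligible among the genes named between vectors. Their mean share was 1.82% of reads, against 0.0143% in set C and 0.0164% in set A, and 80 of its 181 nuclei had over 1%. Deeper sequencing of the set is argued against, since its median of genes per nucleus was 1.20 times that of the other sets at equal reads (1.18 to 1.27 without 1 vector). Rplp0, Rps3, Eef1a1 and Actb, none of them mitochondrial, averaged 4.73 in the set and 2.82 in the others, a difference of 1.91 on the log2 scale, so cytoplasm or whole cells in part of the set may be the source. No biological explanation was tested.

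The nuclei labelled striatum held no SPN-like cluster. A selection of other striatal cells by the vectors is argued against, since glutamatergic neuron-like nuclei, a class the striatum lacks, were 53.5% of all. For loss of SPNs in the clustering, 0 of 781 nuclei had reads of 4 D1 or D2 genes together with 3 of Ppp1r1b, Adcy5, Rgs9 and Rarb. At least 4 D1 genes alone were read in 2 nuclei, and at least 4 D2 genes in 2. How often real SPNs would pass these rules was not measured, so the counts argue against such a loss only as far as the rules would catch SPNs. Of the glutamatergic nuclei, 78.5% had a read of Tbr1, Neurod6, Neurod2 or Emx1. These genes belong to the list that named the glutamatergic clusters, so this share was partly set by the naming. It cannot decide whether the nuclei came from cortical tissue under a striatum label, which remains a candidate explanation. Hippocampus and amygdala also use several of these genes and were not set apart.

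The classes of 1 vector label differed between library sets and along the nucleus numbers. A fixed mixture of classes per vector is argued against, since adjacent numbers of 1 vector and set shared a broad class in 91.1% of 704 pairs and numbers at least 8 apart in 75.3% of 4164, a gap of 15.7 percentage points (12.3 to 17.3 without 1 vector). Depth is argued against, since the mean gap in GABAergic share between sets was 42.2 points before and 44.0 after thinning. The state of Xist and Y genes, which tells animals of either sex apart (called at 5 CPM, a limit chosen after seeing the data), ran with the numbers by 23.2 points (98.3% of adjacent and 75.2% of distant pairs), and 12 of 20 labels held nuclei of both states. Several animals or sorts under 1 label, or labels out of step with libraries, may therefore underlie the runs; these were not told apart from each other.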

How the results depend on the processing

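The use of transmitter genes alone, of the largest set for GABAergic shares, of naming on log2(CPM+10) and of leaving out set B was chosen after the data had been seen. No paired analysis was possible because numbers only name single nuclei within a vector. The leading class share of all 20 vectors stayed within its interval without the filter on nuclei, at resolutions 0.5 and 2, with 1500 variable genes, after thinning and for clusters from log2(CPM+10) named on log2(CPM+1). With at least 2000 genes AiE0387m came to 100%. With naming also on log2(CPM+10) the shares were 70% for AiE0078h and AiE0445h_3xC2, 65% for AiE0140h, 71.1% for AiE0387m, 45.9% for AiE0391h, 77.5% for AiE0401h, 53.8% for AiE0779m and 28.9% for hSyn1. With classes from marker levels all 20 fell: AiE0078h 40%, AiE0140h 27.5%, AiE0387m 36.8%, AiE0390m and AiE0450h 20.5%, AiE0391h 24.3%, AiE0401h 17.5%, AiE0410m 22.5%, AiE0445h_3xC2 45%, AiE0447h 18.4%, AiE0452h 7.69%, AiE0475m 25.6%, AiE0600m 13.2%, AiE0682h, AiE0779m and hI56i 23.1%, AiE0743m_3xC2 35%, CMV 25%, DLX2.0 17.9% and hSyn1 10.5%. GABAergic shares by marker levels were 37.5% for CMV, 46.2% for hI56i and 43.6% for DLX2.0, and the difference of h from m enhancers turned to -0.355 percentage points. Marker levels gave each nucleus to the class list with the highest score, with no minimum, and SPN and glial lists were among them. A nucleus given to a list other than the interneuron and glutamatergic ones counted in neither broad class, which lowers these shares. By transmitter genes alone the GABAergic shares of all 4 reference vectors were counted as the same. Why the other lists scored higher was not tested. In the largest set alone the leading class had 100% for AiE0140h, AiE0391h, AiE0445h_3xC2, AiE0779m and hSyn1, 96.7% for AiE0447h, 78.3% for AiE0475m, 62.5% for AiE0410m and CMV, and 54.2% for AiE0390m; GABAergic shares were 95.8% for CMV, 0% for hSyn1 and 100% for hI56i. Without set B the values were 96.9% for AiE0140h, 54.2% for AiE0390m, 62.5% for AiE0410m, 96.7% for AiE0447h and 100% for AiE0391h, AiE0445h_3xC2 and AiE0779m. Both follow from the sets' different make-up. Of the gene differences, none of 104 at pseudocount 10, of 40 from summed reads and of 104 in the largest set changed sign. These genes were picked for the largest differences in the same nuclei, so a kept sign was likely from the start. Their sizes moved: for hSyn1 against CMV, Zdhhc17 came to 0.48 from summed reads, and Chl1 to 0.49 and Mat2a to -6.63 in the largest set. Without the filter on genes 18 of 20 genes named for hSyn1 against CMV and 13 of 20 for DLX2.0 against hI56i remained. The balance of D1 to D2 SPNs was not run for want of such nuclei.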

Other observations

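The layer genes below were chosen after their values had been seen, and the test of h against m enhancers was planned.

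The glutamatergic clusters carried genes known from different layers of the cortex. In 1 cluster of 120 nuclei Rorb, a layer 4 gene, had a read in 57.5% of nuclei. In another of 106 nuclei Lamp5 was read in 85.8% and Cux2, an upper layer gene, in 50.9%. Tle4 (74.0%) and Foxp2 (54.8%), known from layer 6, were highest in a cluster of 73 nuclei, though Tle4 was also read in 66.7% of the smallest cluster, where Tshz2 was read in all 9 nuclei. Fezf2 set no cluster apart, with 32.9% to 44.4% in 4 of them. The Rorb cluster held 120 of all 418 glutamatergic nuclei. Among labels with at least 10 glutamatergic nuclei, its share was highest for CMV (8 of 14, 57.1%, 28.9 to 82.3) and AiE0447h (15 of 29, 51.7%, 32.5 to 70.6). AiE0475m followed with 37.5%. The 29 nuclei of AiE0447h all came from set A, and 13 of the 14 of CMV from set C. The GABAergic clusters likewise carried different marker genes: Pvalb was read in 87.5% of 176 nuclei, Sst in 96.7% of 90, Adarb2 and Npy in 91.9% of 37, and Vip in 83.3% of 24. A further 42 glutamatergic nuclei, all of set B, were led by mitochondrial genes.

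Tac1, a D1 SPN list member that cortical interneurons also use, was read in 26.8% of GABAergic and 0.239% of glutamatergic nuclei. Broad classes from Slc17a7, Gad1 and Gad2 reads alone were the same as those from clusters in 737 of 769 nuclei (95.8%). Enhancers with numbers ending in h had a mean leading class share of 71.3% (SD 25.2, n = 9) and those ending in m 58.4% (SD 25.1, n = 7). The difference of 13 percentage points did not pass a two-sided exact permutation test over 11440 splits (p = 0.311), and its sign turned with classes from marker levels.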
